A study of Homo sapiens with 18 samples.

How the data were processed

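RNA was measured on 18 human whole-transcriptome microarrays, 3 for each of 6 groups. The groups are 2 multiple myeloma-type cell lines, KMS12-BM and JJN3, each exposed for 24 h to the solvent DMSO, to amiloride or to TG003. Per the labels' protocols, amiloride was given at 0.1 mM to KMS12-BM and at 0.4 mM to JJN3, and TG003 at 0.4 mM to both, in RPMI medium with serum at a share that differs between the lines. RNA was extracted with a column kit. The sample labels call the extracted molecule total RNA, whereas the series description speaks of poly A+ RNA.

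The deposited values are log2 expression values that the authors made with RMA (background correction, quantile normalization and probe set summary), per the submitters' processing notes, which give no version. The genome build is not given in the sources used here. The table holds 70523 probe sets, its values lie between 1.88 and 19.84, and the medians of the arrays lie between 4.50 and 4.69. For arrays, the number of replicates limits the precision.

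Probe sets were matched to gene symbols by identifier. Of the 70523, 25324 are listed in the annotation used. Of these, 23781 carry 1 symbol and 1543 carry several. The remaining 45199 are not listed and stay unnamed here, as do those with several symbols. The brightest probe set was taken for 479 genes with more than 1, and 21986 genes had 1, which gives 22465 genes. No symbol needed an update through its Entrez number (0 updated). Background was judged from 92 ERCC control probe sets, whose median was 3.97 and whose 95th percentile, 6.99, serves as the background reference. Some of these probe sets carry signal well above it, with means of 15 for ERCC-00014, 10.46 for ERCC-00099 and 9.7 for ERCC-00145, and whether spike-ins were added is not given in the sources used here, so the reference may not measure background alone. A gene-level value does not separate the isoforms of a gene.

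Groups follow the sample titles. On the third KMS12-BM amiloride array, the cell line field reads JJN3, while its title, source, disease and dose fields give KMS12-BM. It was kept as KMS12-BM, and the values were checked: across genes its mean r was 0.998 with the other KMS12-BM amiloride arrays and 0.932 with the JJN3 amiloride arrays. Its CCND1 value was 14.84, against means of 14.87 in KMS12-BM DMSO and 6.08 in JJN3 DMSO. Its CCND2 value was 5.85, against 5.98 and 15.22. Replicate numbers come from the order of a serial code in the titles, which is the source of any pairing between groups. The codes run in 3 consecutive blocks, each with an array of every group. After group means were removed, 15 of 18 arrays correlated best with arrays of their own number in the other groups. Arrays of the same number correlated above 0.1 for all 3 numbers in 4 of 15 pairs of groups. These include DMSO with TG003 in each line and the lines in DMSO, but no amiloride group with its own DMSO group. The main fit has no replicate block, which was one of the alternatives run.

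Genes were tested with limma 3.58.1 in R 4.3.3, in 1 model with 6 group means and 12 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all 22465 genes and a threshold of 0.05. There were 9 contrasts: each drug against DMSO in each line, the lines in DMSO, the difference between the lines in the response to each drug, and one drug against the other in each line. Gene lists, 37 with 1045 members of which 889 were measured, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The contrasts, the lists, the limma and camera tests, the rule for named genes and the alternatives were fixed before the data were examined. Exceptions chosen after seeing the data are the medians and calls of single lists under the scaling alternatives and the tests so described in the closing observations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.

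Named genes are the 8 with the largest rises and the 8 with the largest falls at an adjusted p under 0.05 whose groups do not overlap (5 and 5, without that condition, for differences in response), leaving out immunoglobulin and T cell receptor segments, sex-linked marker genes, small RNA genes and provisional symbols. Further named genes are up to 4 members of each list with the largest change at an adjusted p under 0.05, or else 1 with the smallest p. CLK1 to CLK4, SCNN1A, CCND1, CCND2, MAF, ITGB7 and MYC are always named where their comparison applies. Of 927 named calls between 2 groups, all 3 arrays of one group lay above all 3 of the other in 919. The calls were chosen by their adjusted p, and part of them by this separation, so the count describes them and tests nothing. The labels do not say whether the 3 arrays of a group are separate cultures, so the p-values may measure technical spread alone.

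The analysis was tested on simulated data with 22465 genes. It recovered 64% of 50 genes changed by 0.5 on the log2 scale and 100% of 50 changed by 1, and it called 10 of 22265 unchanged genes. The simulated noise was normal and independent between genes, without replicate structure. These counts hold for that setting and do not give the error rate on the real arrays. Alternatives were only the groups compared, a variance prior with trend and robust estimation, genes without the 40% dimmest, the mean of a gene's probe sets, arrays centred on their median, a further quantile normalization, array weights, a replicate block, each array left out in turn, all probe sets, camera on ranks, and overlaps at an adjusted p under 0.01 or with at least 2-fold changes.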

Results

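The 18 arrays measured RNA in KMS12-BM and JJN3, 2 established human plasma cell tumour lines. KMS12-BM is labelled multiple myeloma and carries an immunoglobulin translocation that activates the cyclin D1 gene CCND1, and JJN3 is labelled plasma cell leukemia and carries one that activates the transcription factor gene MAF. Each line was exposed for 24 h to DMSO, to amiloride or to TG003, with 3 arrays per group. Amiloride is a potassium-sparing diuretic that blocks the epithelial sodium channel, and TG003 inhibits kinases of the CLK family, which phosphorylate SR splicing factors. Amiloride was given at 0.1 mM to KMS12-BM and 0.4 mM to JJN3, so its dose differs with the line, while TG003 was given at 0.4 mM to both. Values are log2 intensities. Changes are differences of group means ± SE from limma with n = 3 per group, adjusted p-values of genes come from limma, and those of lists come from camera. Within groups the correlation between arrays across genes was 0.9955 to 0.9984, and 8315 of 22465 genes lay above the background reference of 6.99 in at least 1 group. All 3 arrays of one group lay on the stated side of all 3 of the other in 919 of 927 named calls between 2 groups, which include each called gene given a value here for such a comparison.

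Amiloride at 0.1 mM changed 6865 genes in KMS12-BM. Of 35 integrated stress response genes 25 rose, while 32 of 43 DNA replication genes and 17 of 21 cholesterol synthesis genes fell. These 3 lists passed at the preset correlation and not at an estimated one (adjusted p = 0.3, 0.27 and 0.081 with an estimated correlation). DDIT3, the stress transcription factor CHOP, rose by 2.77 ± 0.19 on the log2 scale (adjusted p = 1.5e-08). RRM2, the small subunit of ribonucleotide reductase, changed by -2.98 ± 0.12 (adjusted p = 1.1e-10), and DHCR7, which makes the last step of cholesterol synthesis, by -3.00 ± 0.19 (adjusted p = 5.7e-09). Of the called genes 3810 rose and 3055 fell, and 1409 changed at least 2-fold, 790 up and 619 down. Of all called genes, 69.6% had a group mean above the background reference.

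The largest rises included KMO, which hydroxylates kynurenine, at 3.64 ± 0.17 (adjusted p = 2.9e-10), the monocarboxylate carrier SLC16A4 at 3.29 ± 0.14, and TAF5, a subunit of the transcription factor TFIID, at 3.24 ± 0.17. TCP11L2 rose by 3.72 ± 0.24, KLHL24 by 3.43 ± 0.21, BRI3 by 3.24 ± 0.23, the zinc finger gene HIVEP2 by 3.02 ± 0.12 and CREBRF by 2.98 ± 0.19. The largest falls were in LPCAT3, which remodels phospholipids, at -4.25 ± 0.16 (adjusted p = 7.3e-11), the adaptor gene SLA2 at -3.80 ± 0.17, TAF9B, another TFIID subunit, at -3.51 ± 0.13, and FAM111B at -3.34 ± 0.13. SEPTIN3 changed by -3.32 ± 0.12, the DNA polymerase alpha subunit gene POLA2 by -3.23 ± 0.21, the chromatin assembly factor gene CHAF1B by -3.19 ± 0.16 and the aldolase gene ALDOC by -3.10 ± 0.14. The lower group lay below the background reference for TCP11L2, KMO, SLC16A4, CREBRF, SLA2, ALDOC, DDIT3 and CTH.

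Of 35 measured genes of the integrated stress response driven by the transcription factor ATF4, 25 rose, 2 fell and 8 did not pass, with the same 25 and 2 when adjusted over the list alone, and their median was 0.76 (adjusted p = 1.2e-09, and adjusted p = 0.3 with an estimated correlation). Examples are CTH, which makes cysteine, at 2.43 ± 0.23, the seryl-tRNA synthetase gene SARS1 at 2.40 ± 0.16 and the amino acid carrier gene SLC3A2 at 2.13 ± 0.12. Of 21 cholesterol synthesis genes 17 fell and 1 rose, also 17 and 1 adjusted over the list alone. Their median was -0.81 (adjusted p = 6.1e-10, and adjusted p = 0.081 with an estimated correlation). ACAT2 changed by -2.47 ± 0.09, HMGCS1 by -2.16 ± 0.19 and TMEM97 by -1.79 ± 0.13. Of 43 DNA replication genes 32 fell and 1 rose, and 32 and 1 adjusted over the list alone. Their median was -0.88 (adjusted p = 9.7e-16, and adjusted p = 0.27 with an estimated correlation). Beside RRM2, the replication factor gene MCM10 changed by -2.42 ± 0.11.

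Among 33 glycolysis and hypoxia genes 16 fell and 4 rose, 17 and 4 adjusted over the list alone. Their median was -0.23 (adjusted p = 0.00019, and adjusted p = 0.3 with an estimated correlation) and -0.37 after a further quantile normalization. The collagen hydroxylase gene P4HA1 changed by -1.87 ± 0.18 and the phosphofructokinase gene PFKM by -1.35 ± 0.1, whereas the histone demethylase gene KDM3A rose by 1.35 ± 0.12. Of 32 endoplasmic reticulum chaperone genes 16 fell and 7 rose, 17 and 7 adjusted over the list alone. Their median was -0.28 (adjusted p = 0.012, and adjusted p = 0.59 with an estimated correlation). HSPA5, the chaperone BiP, changed by -2.40 ± 0.16 and PDIA4 by -2.13 ± 0.1, while EDEM1, which acts in the disposal of misfolded proteins, rose by 1.82 ± 0.14. Of 20 genes of oxidative stress under NRF2 10 fell and 2 rose, 12 and 2 adjusted over the list alone. Their median was -0.29 (adjusted p = 0.0025, and adjusted p = 0.081 with an estimated correlation).

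Of 16 genes for kinases of the CLK, DYRK and SRPK families 9 rose and 0 fell, 11 and 0 adjusted over the list alone. Their median was 0.35 (adjusted p = 0.00018, and adjusted p = 0.27 with an estimated correlation). CLK1 rose by 1.80 ± 0.16 (adjusted p = 2.1e-07), CLK3 by 1.41 ± 0.09 and DYRK1A by 1.31 ± 0.12. Of 12 host RNAs of snoRNAs and substrates or factors of nonsense-mediated decay, 9 rose and 1 fell, also 9 and 1 adjusted over the list alone. Their median was 0.83 (adjusted p = 0.00019, and adjusted p = 0.15 with an estimated correlation). UPF2 rose by 1.70, GADD45B by 1.5 and UPF1 by 1.29. Of 23 SR splicing factor genes 11 rose and 3 fell, 11 and 3 adjusted over the list alone. Their median was 0.14 (adjusted p = 0.012, and adjusted p = 0.71 with an estimated correlation), but it was -0.01 after a further quantile normalization (adjusted p = 0.16). Of 24 NF-kB target genes 10 rose and 2 fell, 11 and 2 adjusted over the list alone. Their median was 0.24 (adjusted p = 0.019, and adjusted p = 0.39 with an estimated correlation), and the adhesion gene ICAM1 rose by 2.67 ± 0.28. Of 29 autophagy and lysosome genes 15 rose and 4 fell, 15 and 4 adjusted over the list alone. Their median was 0.29 (adjusted p = 0.0075, and adjusted p = 0.59 with an estimated correlation) and shrank to 0.16 after a further quantile normalization, with BECN1 at 1.64. Of 30 regulators of apoptosis 15 rose and 5 fell, 15 and 5 adjusted over the list alone. Their median was 0.28 (adjusted p = 0.012, and adjusted p = 0.32 with an estimated correlation), with the death receptor gene TNFRSF10B at 1.36.

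The sodium channel gene SCNN1A, a target of amiloride, changed by -0.17 ± 0.05 (adjusted p = 0.015) at a level below the background reference, and this call ended without KMS12-BM DMSO array 1 or amiloride array 3, with only the groups compared and with quantile normalization. Of 14 amiloride-sensitive channel and exchanger genes 2 rose and 3 fell, 2 and 3 adjusted over the list alone (median -0.07, adjusted p = 0.52). Of 14 reference genes often taken as stable 7 fell and 2 rose, 9 and 4 adjusted over the list alone. Their median was -0.39 (adjusted p = 0.023, and adjusted p = 0.32 with an estimated correlation), with ACTB at -1.03, and the direction held with arrays centred on their median and with quantile normalization. Markers of other cell types gave medians of -0.09 for T and NK cells (adjusted p = 0.15), -0.01 for myeloid cells (adjusted p = 0.8), -0.04 for stromal and endothelial cells (adjusted p = 0.53) and -0.10 for erythroid cells (adjusted p = 0.53).

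**Figure D1:**
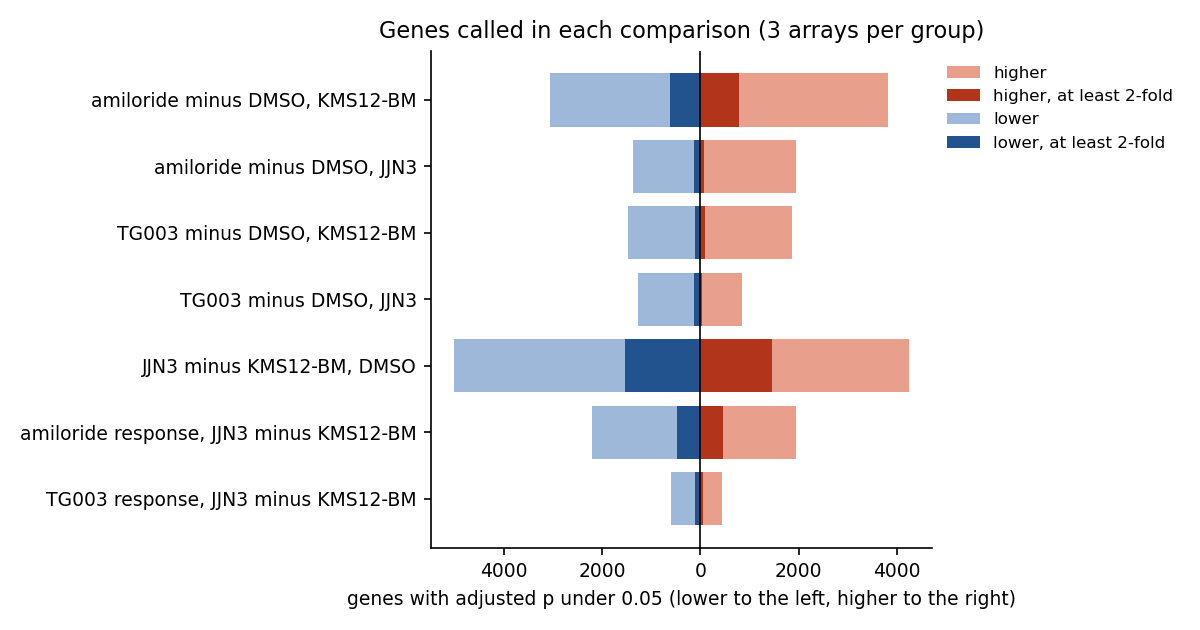
Number of genes with an adjusted p under 0.05 in each comparison (horizontal axis, lower to the left and higher to the right of 0), with those changed at least 2-fold in the darker shade. Amiloride changed 6865 genes in KMS12-BM and 3317 in JJN3, TG003 changed 3330 and 2107, and 9258 differed between the lines in DMSO.

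Amiloride at 0.4 mM changed 3317 genes in JJN3, where 26 of 33 glycolysis and hypoxia genes and 17 of 21 cholesterol synthesis genes fell, as did 18 of 43 DNA replication genes and 20 of 40 mitosis genes. The first pair of lists passed at both correlations, and the second did not with an estimated correlation (adjusted p = 0.27 for each). PDK1, which restrains pyruvate entry into the citrate cycle, changed by -2.38 ± 0.1 (adjusted p = 3.4e-09), and ALDOC by -2.63 ± 0.14 (adjusted p = 2e-08). PHGDH, the first enzyme of serine synthesis, changed by -1.70 ± 0.13 (adjusted p = 8.6e-07). CYP1B1, a target of the aryl hydrocarbon receptor AHR, rose by 1.91 ± 0.17 (adjusted p = 3.2e-06). Of the called genes 1943 rose and 1374 fell, 197 changed at least 2-fold, 72 up and 125 down, and 76.6% had a group mean above the background reference.

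Other large rises were in CLEC2B at 1.87 ± 0.22, the chemokine receptor gene CCR2 at 1.74 ± 0.15, the MAP kinase phosphatase gene DUSP6 at 1.71 ± 0.19, HEXIM1, which inhibits transcription elongation, at 1.63 ± 0.13, and BHLHE41 at 1.62 ± 0.09. The ribosome biogenesis gene RRS1 rose by 1.57 ± 0.19. The largest falls included LAMP5 at -2.75 ± 0.23, the adenosine deaminase gene ADA at -2.59 ± 0.15 (adjusted p = 6.4e-08), RGS1 at -2.47 ± 0.28 and the chemokine gene CCL3 at -2.24 ± 0.28. The DMSO level of CYP1B1 lay below the background reference.

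Of 33 glycolysis and hypoxia genes 26 fell and 0 rose, 29 and 0 adjusted over the list alone, with a median of -0.50, and the list passed with the preset and with an estimated correlation (adjusted p = 6.7e-24 and 0.0096). P4HA1 changed by -2.00 ± 0.18. Of 21 cholesterol synthesis genes 17 fell and 0 rose, 19 and 0 adjusted over the list alone. Their median was -0.58 (adjusted p = 3e-15, and adjusted p = 0.016 with an estimated correlation). INSIG1, a sterol sensor partner, changed by -2.03 ± 0.23, HMGCS1 by -1.80 ± 0.19 and DHCR7 by -1.49 ± 0.19. Of 9 AHR target genes 3 rose and 0 fell, 4 and 0 adjusted over the list alone. Their median was 0.27 (adjusted p = 0.00078, and adjusted p = 0.031 with an estimated correlation), and the quinone reductase gene NQO1 rose by 1.01 ± 0.14.

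Of 35 integrated stress response genes 14 fell and 0 rose, 17 and 0 adjusted over the list alone. Their median was -0.32 (adjusted p = 3.9e-09, and adjusted p = 0.27 with an estimated correlation). ALDH1L2, a mitochondrial folate enzyme, changed by -1.96 ± 0.19 and the tRNA exporter gene XPOT by -1.53 ± 0.15. Of 43 DNA replication genes 18 fell and 0 rose, 25 and 0 adjusted over the list alone. Their median was -0.30 (adjusted p = 8.1e-12, and adjusted p = 0.27 with an estimated correlation), with CDC45 at -1.35 ± 0.11 and the thymidine kinase gene TK1 at -1.55 ± 0.22. Of 40 mitosis genes 20 fell and 0 rose, 25 and 1 adjusted over the list alone. Their median was -0.36 (adjusted p = 1.9e-10, and adjusted p = 0.27 with an estimated correlation), with the kinesin gene KIF20A at -1.24 ± 0.14. Of 32 endoplasmic reticulum chaperone genes 9 fell and 0 rose, 14 and 4 adjusted over the list alone. Their median was -0.17 (adjusted p = 0.0014, and adjusted p = 0.31 with an estimated correlation).

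Of 49 core spliceosome genes 14 rose and 2 fell, 16 and 4 adjusted over the list alone. Their median was 0.21 (adjusted p = 3.4e-07, and adjusted p = 0.27 with an estimated correlation), with PRPF3 at 0.93 and DHX16 at 0.86. Of 23 SR splicing factor genes 9 rose and 0 fell, 11 and 0 adjusted over the list alone. Their median was 0.24 (adjusted p = 7.2e-07, and adjusted p = 0.27 with an estimated correlation), with SRSF8 at 0.82 ± 0.11. Of 19 hnRNP genes 7 rose and 0 fell, 7 and 0 adjusted over the list alone. Their median was 0.19 (adjusted p = 0.00055, and adjusted p = 0.3 with an estimated correlation). Of 16 CLK, DYRK and SRPK kinase genes 5 rose and 0 fell, 7 and 0 adjusted over the list alone. Their median was 0.19 (adjusted p = 0.0014, and adjusted p = 0.27 with an estimated correlation), with CLK1 at 0.83 ± 0.16 and PRP4K at 0.97 ± 0.11. Of 32 MYC target and ribosome biogenesis genes 11 rose and 2 fell, 12 and 3 adjusted over the list alone. Their median was 0.20 (adjusted p = 0.00014, and adjusted p = 0.34 with an estimated correlation) and 0.13 after a further quantile normalization, with the nucleolar gene NOP2 at 1.13. Of 30 proteasome genes 5 rose and 0 fell, 8 and 1 adjusted over the list alone. Their median was 0.22 (adjusted p = 0.00036, and adjusted p = 0.42 with an estimated correlation), with PSMD12 at 0.95.

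Of 24 plasma cell markers 5 fell and 1 rose, 6 and 1 adjusted over the list alone. Their median was -0.16 (adjusted p = 0.024, and adjusted p = 0.31 with an estimated correlation), and of 25 B cell markers 6 fell and 1 rose, 6 and 1 adjusted over the list alone. Their median was -0.05 (adjusted p = 0.038, and adjusted p = 0.3 with an estimated correlation) and -0.02 under each of the scaling alternatives, where the call ended with quantile normalization (adjusted p = 0.12). CIITA, the master regulator of HLA class II genes, changed by -1.16 and HLA-DPA1 by -1.15. SCNN1A changed by 0.00 ± 0.05 (adjusted p = 0.99), below the background reference, while the exchanger gene SLC9A9 rose by 1.41 ± 0.18 (adjusted p = 6.6e-05). Of 14 reference genes 7 fell and 2 rose, 7 and 2 adjusted over the list alone. Their median was -0.24 (adjusted p = 0.016, and adjusted p = 0.27 with an estimated correlation). Markers of other cell types gave medians of -0.02 for T and NK cells (mean 0.02, test upward, adjusted p = 0.89), -0.04 for myeloid cells (adjusted p = 0.28), -0.04 for stromal and endothelial cells (adjusted p = 0.67) and -0.06 for erythroid cells (adjusted p = 0.16). Without JJN3 amiloride array 3 the plasma cell list had an adjusted p of 0.13, and the B cell list had one of 0.077 without JJN3 amiloride array 2 and of 0.068 without JJN3 DMSO array 3.

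TG003 at 0.4 mM changed 3330 genes in KMS12-BM, and the genes of all 4 CLK kinases rose, CLK1 by 1.04 ± 0.16 (adjusted p = 0.00032), CLK3 by 0.63 ± 0.09 (adjusted p = 0.00014) and CLK4 by 1.09 ± 0.13 (adjusted p = 5.4e-05), with CLK2 at 0.46 ± 0.1 (adjusted p = 0.0034). TNFRSF17, the plasma cell receptor BCMA, changed by -1.70 ± 0.26 (adjusted p = 0.00032), the chaperone gene HSPA5 by -1.68 ± 0.16 (adjusted p = 6.4e-06) and the hexokinase gene HK2 by -1.32 ± 0.12 (adjusted p = 3.6e-06). Of the called genes 1865 rose and 1465 fell, though rises made up 50% instead of 56% after a further quantile normalization, 194 changed at least 2-fold, 93 up and 101 down, and 72.7% had a group mean above the background reference.

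Large rises included those of the bile acid carrier family gene SLC10A5 at 2.15 ± 0.3, BEND6 at 2.01 ± 0.16, PPP1R3E, a glycogen-targeting phosphatase subunit, at 1.76 ± 0.12 (adjusted p = 3.8e-07), and the zinc finger genes ZNF512 at 1.70 ± 0.12 and ZNF589 at 1.60 ± 0.13. The largest falls were in SEPTIN3 at -2.48 ± 0.12 (adjusted p = 1.5e-08), SLA2 at -2.44 ± 0.17, the ribonuclease gene RNASE6 at -2.42 ± 0.47, the chromatin reader gene ZMYND8 at -2.18 ± 0.14, the costimulatory receptor gene CD27 at -2.04 ± 0.15, ACY3 at -2.04 ± 0.16, the cytokine receptor gene CSF2RB at -1.95 ± 0.09 and SUCLG2 at -1.94 ± 0.11. The lower group lay below the background reference for SLC10A5, BEND6, SLA2 and CLK4, and the TG003 mean of CLK4, 6.98, lay below it too, so the size of its change is uncertain.

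Of 24 plasma cell markers 12 fell and 0 rose, 14 and 0 adjusted over the list alone. Their median was -0.46 (adjusted p = 6.2e-10, and adjusted p = 0.06 with an estimated correlation). CD38 changed by -1.30 ± 0.23 and the B lineage coactivator gene POU2AF1 by -1.23 ± 0.19. Of 25 B cell markers 4 fell and 0 rose, 5 and 0 adjusted over the list alone. Their median was -0.13 (adjusted p = 0.0037, and adjusted p = 0.17 with an estimated correlation). Of 32 endoplasmic reticulum chaperone genes 17 fell and 1 rose, 20 and 1 adjusted over the list alone. Their median was -0.32 (adjusted p = 7.5e-10, and adjusted p = 0.12 with an estimated correlation), with HERPUD1 at -1.36 ± 0.12 and XBP1, the transcription factor of the secretory programme, at -0.95. Of 33 glycolysis and hypoxia genes 15 fell and 0 rose, 19 and 0 adjusted over the list alone. Their median was -0.40 (adjusted p = 5e-11, and adjusted p = 0.094 with an estimated correlation), with PDK1 at -1.17 ± 0.1. Of 32 MYC target and ribosome biogenesis genes 17 fell and 0 rose, 21 and 0 adjusted over the list alone. Their median was -0.42 (adjusted p = 2.1e-11, and adjusted p = 0.15 with an estimated correlation), with the RNA polymerase I subunit gene POLR1B at -0.83 ± 0.06, NIP7 at -0.80 and the polyamine enzyme gene ODC1 at -0.80.

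Of 40 mitosis genes 15 fell and 2 rose, 20 and 2 adjusted over the list alone. Their median was -0.32 (adjusted p = 2.5e-08, and adjusted p = 0.4 with an estimated correlation), with cyclin B1, CCNB1, at -1 ± 0.13 and PLK1 at -0.99. Of 43 DNA replication genes 13 rose and 1 fell, 15 and 2 adjusted over the list alone. Their median was 0.23 (adjusted p = 3.6e-06, and adjusted p = 0.55 with an estimated correlation), with the helicase gene MCM3 at 0.90 ± 0.11 and CHAF1B at 0.90 ± 0.16. Of 35 cytosolic ribosomal protein genes 6 rose and 0 fell, 6 and 0 adjusted over the list alone. Their median was 0.18 (adjusted p = 4.7e-06, and adjusted p = 0.37 with an estimated correlation). Of 30 proteasome genes 8 fell and 0 rose, 10 and 0 adjusted over the list alone. Their median was -0.22 (adjusted p = 1.2e-06, and adjusted p = 0.39 with an estimated correlation). Of 21 cholesterol synthesis genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone. Their median was -0.25 (adjusted p = 0.00089, and adjusted p = 0.31 with an estimated correlation) and -0.11 without KMS12-BM DMSO array 2, with INSIG1 at -1.38 ± 0.23 and HMGCS1 at -1.14 ± 0.19.

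Of 12 snoRNA host and nonsense-mediated decay RNAs 6 rose and 0 fell, 7 and 0 adjusted over the list alone. Their median was 0.43 (adjusted p = 0.00067, and adjusted p = 0.15 with an estimated correlation), with the decay factor genes SMG5 at 1.04 and UPF1 at 0.93. Of 16 CLK, DYRK and SRPK kinase genes 4 rose and 1 fell, 6 and 3 adjusted over the list alone (median 0.05, adjusted p = 0.14), and of 23 SR splicing factor genes 8 rose and 2 fell, 8 and 2 adjusted over the list alone (median 0.06, adjusted p = 0.28). Of 35 integrated stress response genes 5 rose and 0 fell, 5 and 0 adjusted over the list alone. Their median was 0.17 (adjusted p = 0.0087, and adjusted p = 0.66 with an estimated correlation), but without KMS12-BM TG003 array 2 the list had an adjusted p of 0.37. Markers of other cell types gave medians of -0.07 for T and NK cells (adjusted p = 0.15), -0.03 for myeloid cells (adjusted p = 0.28), -0.02 for stromal and endothelial cells (adjusted p = 0.25) and -0.03 for erythroid cells (adjusted p = 0.77).

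**Figure D2:**
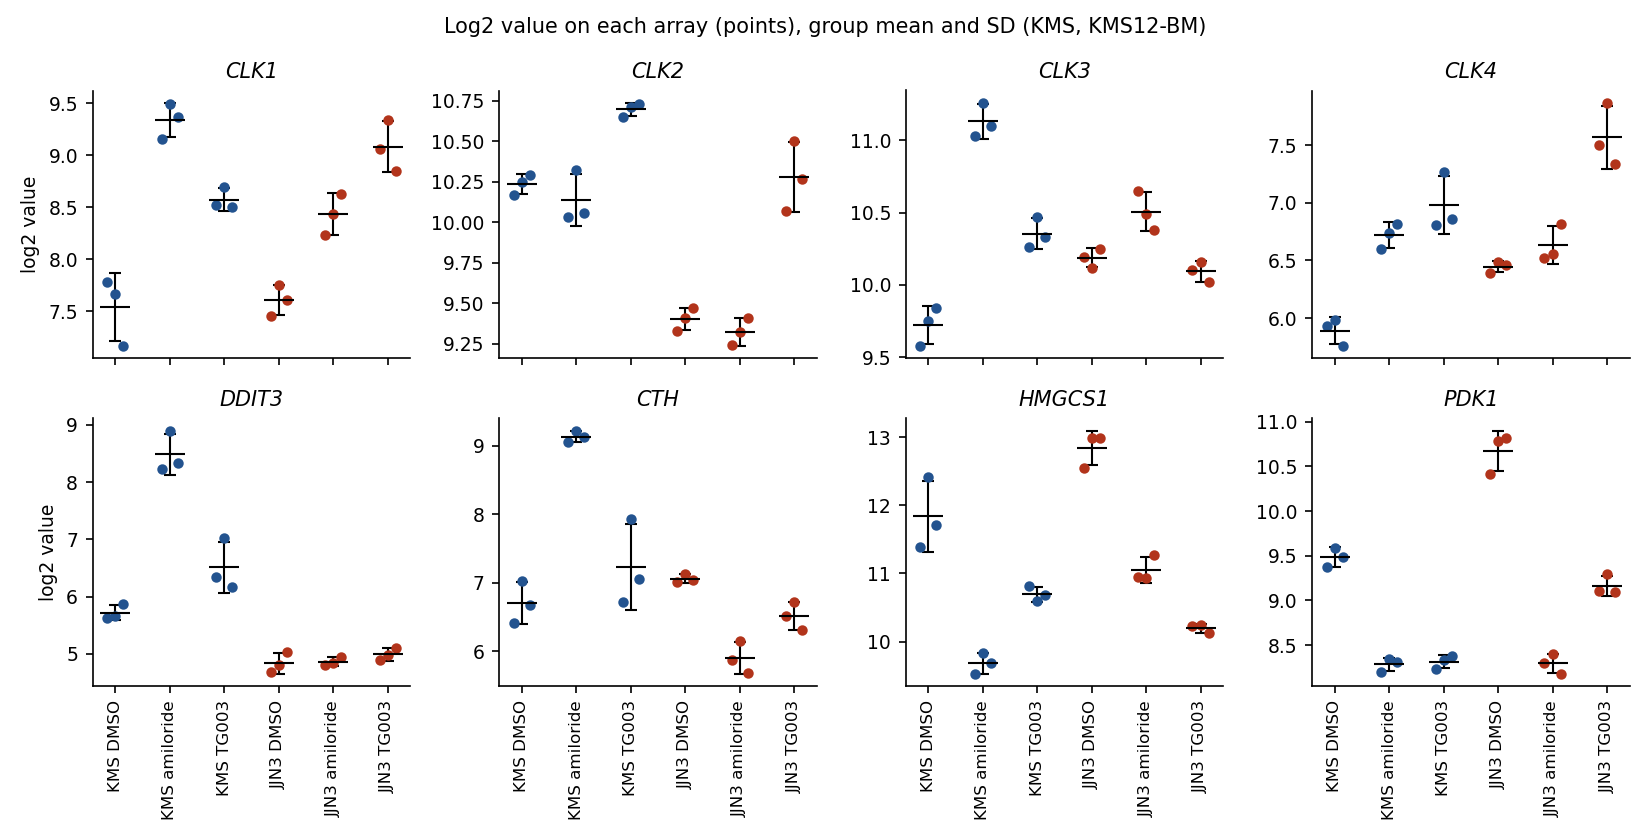
Log2 value on each array (points) with the group mean and SD for CLK1, CLK2, CLK3, CLK4, DDIT3, CTH, HMGCS1 and PDK1 in the 6 groups. DDIT3 reached 8.23 to 8.90 in KMS12-BM with amiloride against 4.80 to 4.95 in JJN3 with amiloride, and CLK3 reached 10.26 to 10.47 in KMS12-BM with TG003 against 9.58 to 9.84 in its DMSO group.

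TG003 at 0.4 mM changed 2107 genes in JJN3, with falls in cholesterol synthesis, glycolysis and plasma cell genes. HMGCS1, which condenses acetyl units early in sterol synthesis, changed by -2.64 ± 0.19 (adjusted p = 8e-07) and INSIG1 by -2.18 ± 0.23 (adjusted p = 1.6e-05). CLK1 rose by 1.48 ± 0.16 (adjusted p = 2.2e-05), CLK2 by 0.88 ± 0.1 (adjusted p = 2.7e-05) and CLK4 by 1.12 ± 0.13 (adjusted p = 6.9e-05), whereas CLK3 changed by -0.09 ± 0.09 (adjusted p = 0.66). Of the called genes 841 rose and 1266 fell, 146 changed at least 2-fold, 25 up and 121 down, and 70.1% had a group mean above the background reference. Array weights, which were 0.41 and 0.38 for JJN3 TG003 arrays 2 and 3, gave 3581 genes.

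Large rises beside CLK1 included LY6G5B at 1.66 ± 0.17, the ephrin gene EFNB2 at 1.42 ± 0.12, TMCC1-DT at 1.37 ± 0.19, TNRC6C-AS1 at 1.33 ± 0.13, the lysosomal peptidase gene TPP1 at 1.33 ± 0.14 and PPP1R3E at 1.29 ± 0.12. Large falls included the AMP deaminase gene AMPD1 at -3.75 ± 0.34, the chemokine genes CCL2 at -3.47 ± 0.28 and CCL3 at -3.40 ± 0.28, the globin pseudogene HBBP1 at -3.12 ± 0.42, ADA at -2.66 ± 0.15 (adjusted p = 1.7e-07) and TNFRSF17 at -2.09 ± 0.26. The lower group lay below the background reference for CLK4, TMCC1-DT, TNRC6C-AS1, PPP1R3E, AMPD1, CCL2, CCL3, TNFRSF17 and CD28.

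Of 33 glycolysis and hypoxia genes 25 fell and 0 rose, 30 and 0 adjusted over the list alone. Their median was -0.66 (adjusted p = 2.4e-31, and adjusted p = 0.0029 with an estimated correlation). ALDOC changed by -1.56 ± 0.14, PDK1 by -1.51 ± 0.1 and P4HA1 by -1.26. Of 21 cholesterol synthesis genes 16 fell and 0 rose, 17 and 1 adjusted over the list alone. Their median was -0.74 (adjusted p = 9e-22, and adjusted p = 0.0037 with an estimated correlation). MSMO1 changed by -1.80 ± 0.14 and the squalene epoxidase gene SQLE by -1.12 ± 0.1. Of 24 plasma cell markers 11 fell and 0 rose, 12 and 0 adjusted over the list alone. Their median was -0.37 (adjusted p = 6e-09, and adjusted p = 0.023 with an estimated correlation), with CD28 at -1.25 ± 0.15. Of 14 genes of the MAF-translocation signature 7 fell and 1 rose, 8 and 1 adjusted over the list alone. Their median was -0.40 (adjusted p = 0.00063, and adjusted p = 0.022 with an estimated correlation), with the chemokine receptor gene CCR1 at -1.87 ± 0.25.

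Of 40 mitosis genes 16 fell and 0 rose, 22 and 0 adjusted over the list alone. Their median was -0.31 (adjusted p = 1.9e-14, and adjusted p = 0.22 with an estimated correlation), with KIF20A at -1.30 ± 0.14 and AURKA at -0.73. Of 32 endoplasmic reticulum chaperone genes 10 fell and 0 rose, 16 and 0 adjusted over the list alone. Their median was -0.22 (adjusted p = 2.3e-06, and adjusted p = 0.2 with an estimated correlation), with HSPA5 at -0.77. Of 12 snoRNA host and nonsense-mediated decay RNAs 5 rose and 0 fell, 7 and 0 adjusted over the list alone. Their median was 0.32 (adjusted p = 0.00015, and adjusted p = 0.082 with an estimated correlation), with the decay kinase gene SMG1 at 0.81 and DANCR at 0.69. Of 20 heat shock genes 4 fell and 0 rose, 5 and 0 adjusted over the list alone. Their median was -0.12 (adjusted p = 0.00044, and adjusted p = 0.32 with an estimated correlation). Of 23 SR splicing factor genes 5 rose and 1 fell, 7 and 1 adjusted over the list alone. Their median was 0.16 (adjusted p = 0.014, and adjusted p = 0.64 with an estimated correlation), and of 16 CLK, DYRK and SRPK kinase genes 4 rose and 0 fell, 4 and 0 adjusted over the list alone (median 0.02, adjusted p = 0.07).

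Of 32 MYC target and ribosome biogenesis genes 2 rose and 1 fell (median 0.00, adjusted p = 0.88), of 43 DNA replication genes 1 rose and 3 fell (median 0.14, adjusted p = 0.15), and of 35 integrated stress response genes 1 rose and 4 fell (median 0.09, adjusted p = 0.8). Of 14 reference genes 2 fell and 0 rose, 4 and 0 adjusted over the list alone. Their median was -0.16 (adjusted p = 0.00042, and adjusted p = 0.097 with an estimated correlation). Markers of other cell types gave medians of 0.05 for T and NK cells (adjusted p = 0.86), 0.00 for myeloid cells (adjusted p = 0.57), 0.02 for stromal and endothelial cells (adjusted p = 0.88) and 0.02 for erythroid cells (mean -0.32, adjusted p = 0.27). The SR splicing factor list had an adjusted p of 0.52 without JJN3 TG003 array 2 and of 0.061 without JJN3 DMSO array 3.

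**Figure D3:**
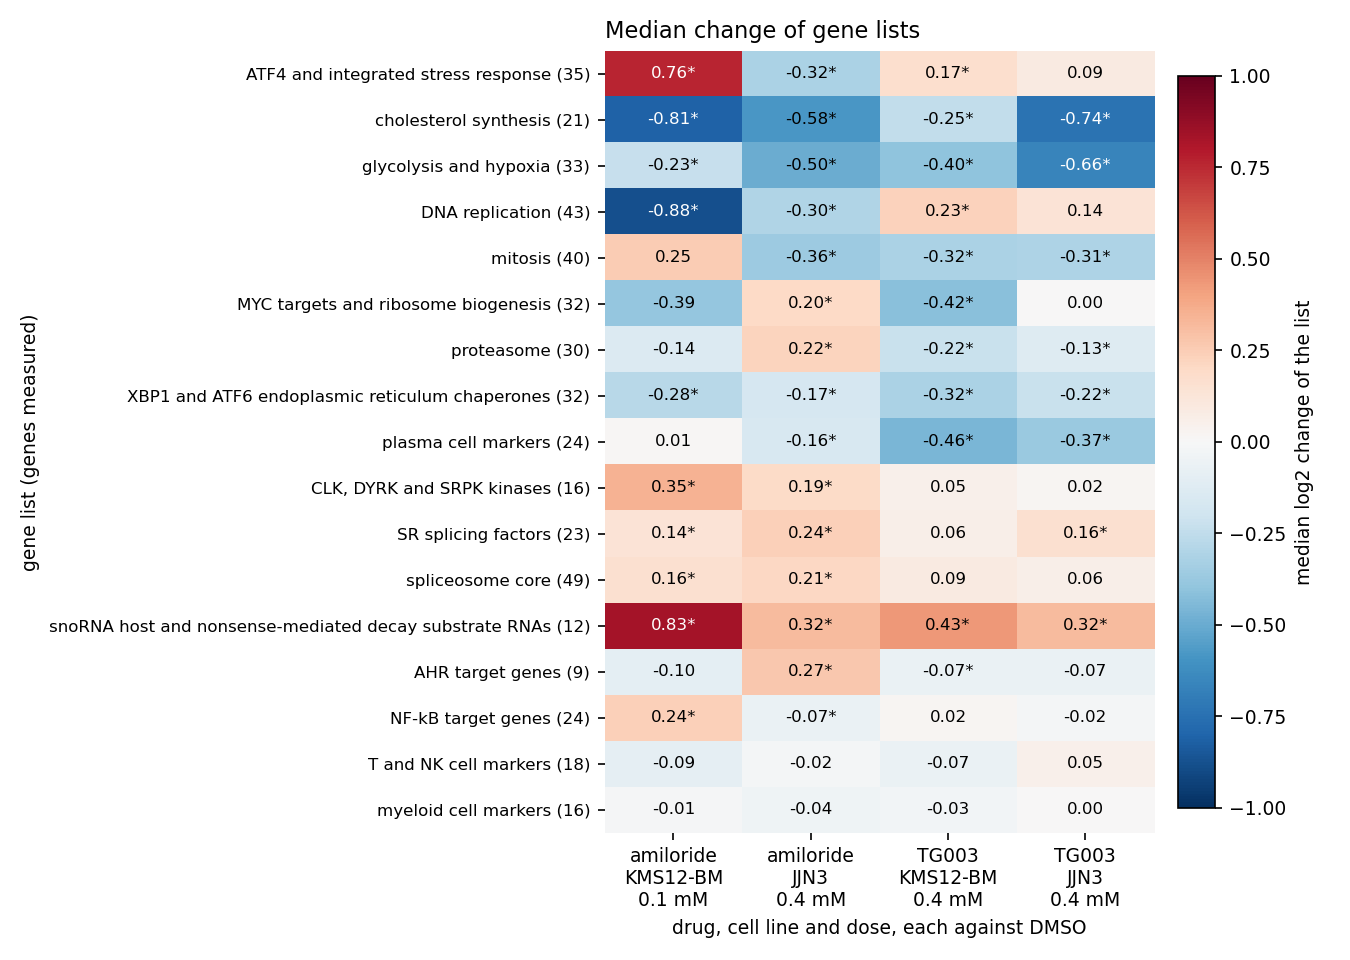
Median log2 change against DMSO (colour and number) of gene lists, with the genes measured in each, for the 2 drugs in the 2 lines, where an asterisk marks an adjusted p under 0.05 at the preset correlation. Glycolysis and hypoxia genes had medians of -0.23 and -0.50 under amiloride and of -0.40 and -0.66 under TG003, in KMS12-BM and JJN3 respectively.

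In DMSO, 9258 genes differed between the lines, and the genes activated by each line's translocation were among them. The serum share of the medium also differed with the line, so line and serum cannot be told apart here or in the differences in response. CCND1 was lower in JJN3 by -8.79 ± 0.16 (adjusted p = 3.7e-16), whereas CCND2 was higher by 9.24 ± 0.12 (adjusted p = 6.8e-18) and MAF by 6.32 ± 0.18 (adjusted p = 9.9e-14). The integrin gene ITGB7, a MAF target, was higher by 4.34 ± 0.19 (adjusted p = 1.2e-11), and MYC differed by 0.22 ± 0.12 (adjusted p = 0.19). Of the called genes 4245 were higher and 5013 lower in JJN3, and of 3003 that differed at least 2-fold 1464 were higher and 1539 lower. Of all called genes, 63.2% had a group mean above the background reference.

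JJN3 carried higher values of the HLA class II gene HLA-DRA at 12.18 ± 0.13 (adjusted p = 9.6e-19), of the growth factor gene HGF at 11.82 ± 0.09 (adjusted p = 1.9e-20) and of JCHAIN, which joins secreted immunoglobulin polymers, at 11.09 ± 0.16 (adjusted p = 2.5e-17). HLA-DRB1 and HLA-DRB5 differed by 11.82 ± 0.17 and 12.34 ± 0.15, and since such paralogs can share probes their values are not separate evidence. KMS12-BM carried higher values of GTSF1, which differed by -11.57 ± 0.14 (adjusted p = 2.1e-18), and also of CD27 at -8.77 ± 0.15, the adaptor gene BLNK at -7.65, CD37 at -7.27 and the kinase gene BTK at -7.12. The lower line lay below the background reference for each of these genes except ITGB7 and MYC, so the size of those differences is uncertain.

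Of 14 genes of the MAF-translocation signature 10 were higher and 1 lower in JJN3, also 10 and 1 adjusted over the list alone. Their median was 3.03 (adjusted p = 4.5e-08, and adjusted p = 0.0011 with an estimated correlation), with CCR1 at 7.84 ± 0.25. Of 33 glycolysis and hypoxia genes 24 were higher and 4 lower, and 24 and 4 adjusted over the list alone. Their median was 0.65 (adjusted p = 1.5e-05, and adjusted p = 0.4 with an estimated correlation), with NDRG1 at 7.41 ± 0.14 and P4HA1 at 1.95. Of 21 cholesterol synthesis genes 14 were higher and 5 lower, and 14 and 5 adjusted over the list alone. Their median was 0.62 (adjusted p = 0.015, and adjusted p = 0.77 with an estimated correlation), with INSIG1 at 3.40 ± 0.23. Of 38 interferon response genes 18 were higher and 6 lower, 19 and 6 adjusted over the list alone. Their median was 0.16 (adjusted p = 0.01, and adjusted p = 0.54 with an estimated correlation), with SAMD9L at 6.69 and OAS2 at -6.90. Of 24 NF-kB target genes 11 were higher and 4 lower, 13 and 5 adjusted over the list alone. Their median was 0.21 (adjusted p = 0.015, and adjusted p = 0.59 with an estimated correlation). Of 24 plasma cell markers 10 were higher and 9 lower (median 0.02, adjusted p = 0.79), with CD38 at -5.51. Markers of other cell types gave medians of -0.04 for T and NK cells (adjusted p = 0.79), 0.03 for myeloid cells (adjusted p = 0.79), 0.03 for stromal and endothelial cells (adjusted p = 0.13) and -0.03 for erythroid cells (adjusted p = 0.58).

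The responses of the lines to amiloride differed for 4148 genes by a test of the difference. CTH rose by 2.43 ± 0.23 in KMS12-BM and changed by -1.15 in JJN3, a difference of -3.58 ± 0.32 (adjusted p = 1.9e-06), whose size is uncertain because its means in KMS12-BM DMSO and JJN3 amiloride lay below the background reference. Of 35 integrated stress response genes 27 had a lower and 0 a higher response in JJN3, 30 and 0 adjusted over the list alone. Their median was -1.39 (adjusted p = 3.9e-22, and adjusted p = 0.1 with an estimated correlation). Of 9 AHR target genes 5 had a higher and 0 a lower response in JJN3, 5 and 0 adjusted over the list alone. Their median was 0.67 (adjusted p = 0.00014, and adjusted p = 0.032 with an estimated correlation). Among the 4148 genes the response was higher in JJN3 for 1951 and lower for 2197, and 927 differed at least 2-fold, but 50.5% of called genes were higher after a further quantile normalization and 50.8% without JJN3 amiloride array 3, against 47.0%. Dose and line cannot be told apart in this contrast, since no line was measured at both doses of amiloride. The serum share of the medium differed with the line too.

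Of 43 DNA replication genes 18 had a higher and 0 a lower response in JJN3, 20 and 1 adjusted over the list alone. Their median was 0.40 (adjusted p = 7.8e-10, and adjusted p = 0.47 with an estimated correlation). Of 40 mitosis genes 20 had a lower and 1 a higher response in JJN3, 23 and 1 adjusted over the list alone. Their median was -0.48 (adjusted p = 3.2e-08, and adjusted p = 0.52 with an estimated correlation). In KMS12-BM with amiloride, 17 of the 40 rose and 7 fell, 18 and 8 adjusted over the list alone, and the list did not pass (median 0.25, adjusted p = 0.11), with HMMR at 1.89 ± 0.12. Of 24 NF-kB target genes 13 had a lower and 1 a higher response in JJN3, 14 and 1 adjusted over the list alone. Their median was -0.56 (adjusted p = 9.4e-06, and adjusted p = 0.1 with an estimated correlation). Of 32 MYC target and ribosome biogenesis genes 14 had a higher and 2 a lower response, 20 and 3 adjusted over the list alone. Their median was 0.47 (adjusted p = 1.2e-06, and adjusted p = 0.47 with an estimated correlation).

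The lines shared part of the amiloride response. With amiloride 1215 genes rose in both lines, against 329.5 expected from the counts in each, and 777 fell in both, against 186.8. Called changes in opposite directions numbered 207, against 497.3 expected. Across genes the log2 changes of the lines correlated with Pearson's r of 0.48 and Spearman's rho of 0.41, and genes are not independent replicates. Expected counts, here and for the other overlaps, treat all 22465 genes alike. Most called genes had a group mean above the background reference, which 8315 genes reached, so the expected counts are likely too low.

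**Figure D4:**
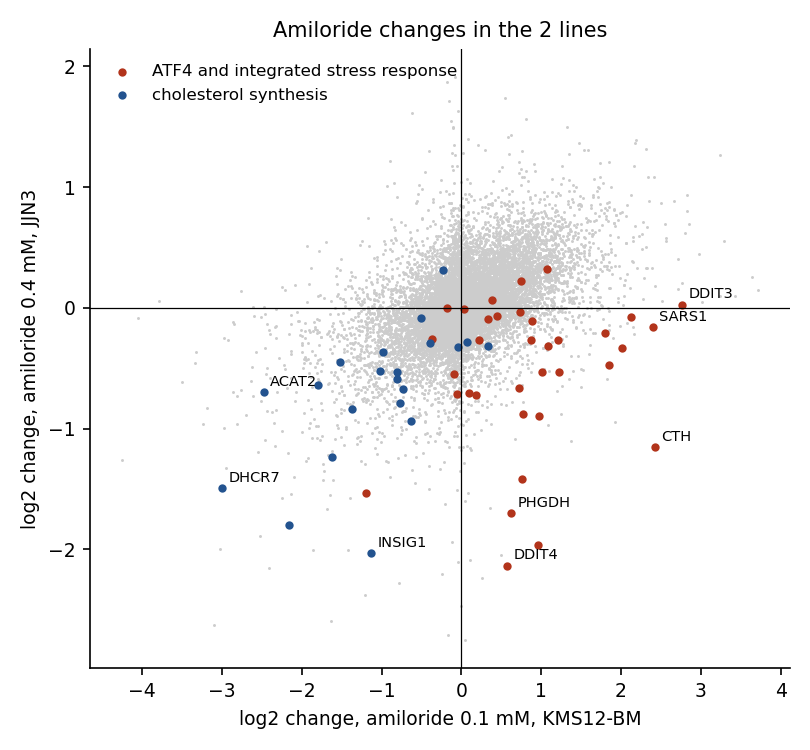
Log2 change with amiloride in KMS12-BM at 0.1 mM (horizontal) against JJN3 at 0.4 mM (vertical), 1 grey point per gene, with integrated stress response genes in red and cholesterol synthesis genes in blue. SARS1 and DDIT3 lie far to the right with changes of 2.40 and 2.77 in KMS12-BM, and DHCR7 lies at the lower left with -3.00 and -1.49.

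The responses of the lines to TG003 differed for 1026 genes by a test of the difference. The dose was the same, but the serum share of the medium differed with the line. CCL2 differed by -3.37 ± 0.39 and CLK3 by -0.72 ± 0.12 (adjusted p = 0.0034). In one line CCL2 lay below the background reference with DMSO and with TG003. A change there could be missed, so its difference is uncertain. Of 21 cholesterol synthesis genes 8 had a lower and 0 a higher response in JJN3, 15 and 0 adjusted over the list alone. Their median was -0.58 (adjusted p = 2.8e-10, and adjusted p = 0.13 with an estimated correlation). Of 32 MYC target and ribosome biogenesis genes 9 had a higher and 0 a lower response, 14 and 1 adjusted over the list alone. Their median was 0.33 (adjusted p = 4.3e-10, and adjusted p = 0.58 with an estimated correlation). The response was higher in JJN3 for 432 genes and lower for 594, and 159 differed at least 2-fold, but the balance turned after a further quantile normalization, with 51.2% of 1302 genes higher against 42.1%. Array weights gave 2262 genes. Without JJN3 DMSO array 2 the count was 677, and without KMS12-BM DMSO array 1 it was 679. With TG003 412 genes rose in both lines, against 69.82 expected, and 467 fell in both, against 82.56, while 48 changed in opposite directions, against 159.9.

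Amiloride and TG003 at the same 0.4 mM differed for 3807 genes in JJN3, with 2366 higher and 1441 lower under amiloride, and 239 differed at least 2-fold. Array weights gave 5872 genes, and the share higher under amiloride, 62.1%, was 55.3% with them, 54.2% after a further quantile normalization and 70.8% with arrays centred on their median. CLK2 was lower under amiloride by -0.96 ± 0.1 (adjusted p = 7.8e-06) and CLK1 by -0.65 ± 0.16 (adjusted p = 0.0084), whereas CYP1B1 was higher by 2.25. The size of the CYP1B1 difference is uncertain, since its TG003 mean lay below its DMSO mean and so below the background reference. Of 14 genes of the MAF-translocation signature 7 were higher and 0 lower under amiloride, 8 and 0 adjusted over the list alone. Their median was 0.47 (adjusted p = 9.3e-06, and adjusted p = 0.0089 with an estimated correlation). Of 43 DNA replication genes 28 were lower and 1 higher, 31 and 1 adjusted over the list alone. Their median was -0.46 (adjusted p = 4.1e-13, and adjusted p = 0.33 with an estimated correlation), with TK1 at -1.73 and CHAF1B at -1.24. Of 35 integrated stress response genes 15 were lower and 0 higher, 19 and 0 adjusted over the list alone. Their median was -0.45 (adjusted p = 3.7e-08, and adjusted p = 0.33 with an estimated correlation), with PHGDH at -1.95. Of 30 proteasome genes 13 were higher and 0 lower, 16 and 0 adjusted over the list alone. Their median was 0.36 (adjusted p = 2.2e-09, and adjusted p = 0.33 with an estimated correlation), with PSMD12 at 1.10. Of 20 heat shock genes 9 were higher and 0 lower, 11 and 0 adjusted over the list alone. Their median was 0.29 (adjusted p = 1e-06, and adjusted p = 0.31 with an estimated correlation), with HSPA4L at 1.15.

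In KMS12-BM, where the doses differed at 0.1 mM for amiloride and 0.4 mM for TG003, the drugs differed for 6686 genes, 3547 higher and 3139 lower under amiloride, and 1368 differed at least 2-fold. CHAF1B was lower under amiloride by -4.10 ± 0.16 (adjusted p = 7.5e-11) and POLA2 by -3.69, while HMMR was higher by 2.87. Of 43 DNA replication genes 34 were lower and 1 higher, 37 and 1 adjusted over the list alone. Their median was -1.12 (adjusted p = 6.5e-24, and adjusted p = 0.24 with an estimated correlation). Of 40 mitosis genes 23 were higher and 3 lower, 23 and 4 adjusted over the list alone. Their median was 0.48 (adjusted p = 1.3e-05, and adjusted p = 0.56 with an estimated correlation). Of 35 integrated stress response genes 21 were higher and 2 lower, 21 and 3 adjusted over the list alone. Their median was 0.68 (adjusted p = 6.9e-07, and adjusted p = 0.51 with an estimated correlation), with SARS1 at 1.87. Of 24 plasma cell markers 12 were higher and 2 lower, 13 and 2 adjusted over the list alone. Their median was 0.38 (adjusted p = 0.0019, and adjusted p = 0.43 with an estimated correlation), with TNFRSF17 at 1.83. CLK1 read 9.16 to 9.49 under amiloride against 8.50 to 8.70 under TG003, and CLK3 11.03 to 11.26 against 10.26 to 10.47. CLK2 was lower under amiloride, at 10.03 to 10.32 against 10.65 to 10.73, and CLK4 overlapped. The CLK, DYRK and SRPK kinase list was higher under amiloride (median 0.50). Its call held with each array left out (highest adjusted p = 0.0074) but not with an estimated correlation.

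Within a line the drugs also shared changes. In JJN3 303 genes rose and 479 fell under both drugs, against 72.74 and 77.43 expected, and 147 changed in opposite directions, against 160.9. In KMS12-BM 871 rose and 751 fell under both, against 316.3 and 199.2, and 660 changed in opposite directions, against 502.1. Since calls gather among brighter genes, these expected counts are likely too low, and the excess of opposite changes in KMS12-BM may not be one. Both drugs in a line share the same 3 DMSO arrays, which adds to the correlation of their changes. Pearson's r across genes was 0.31 in KMS12-BM and 0.36 in JJN3, against 0.50 in both from shared DMSO arrays alone in 20 simulations without drug effects, but the covariance was 0.0399 against 0.0064 in KMS12-BM and 0.0238 against 0.00638 in JJN3.

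**Figure D5:**
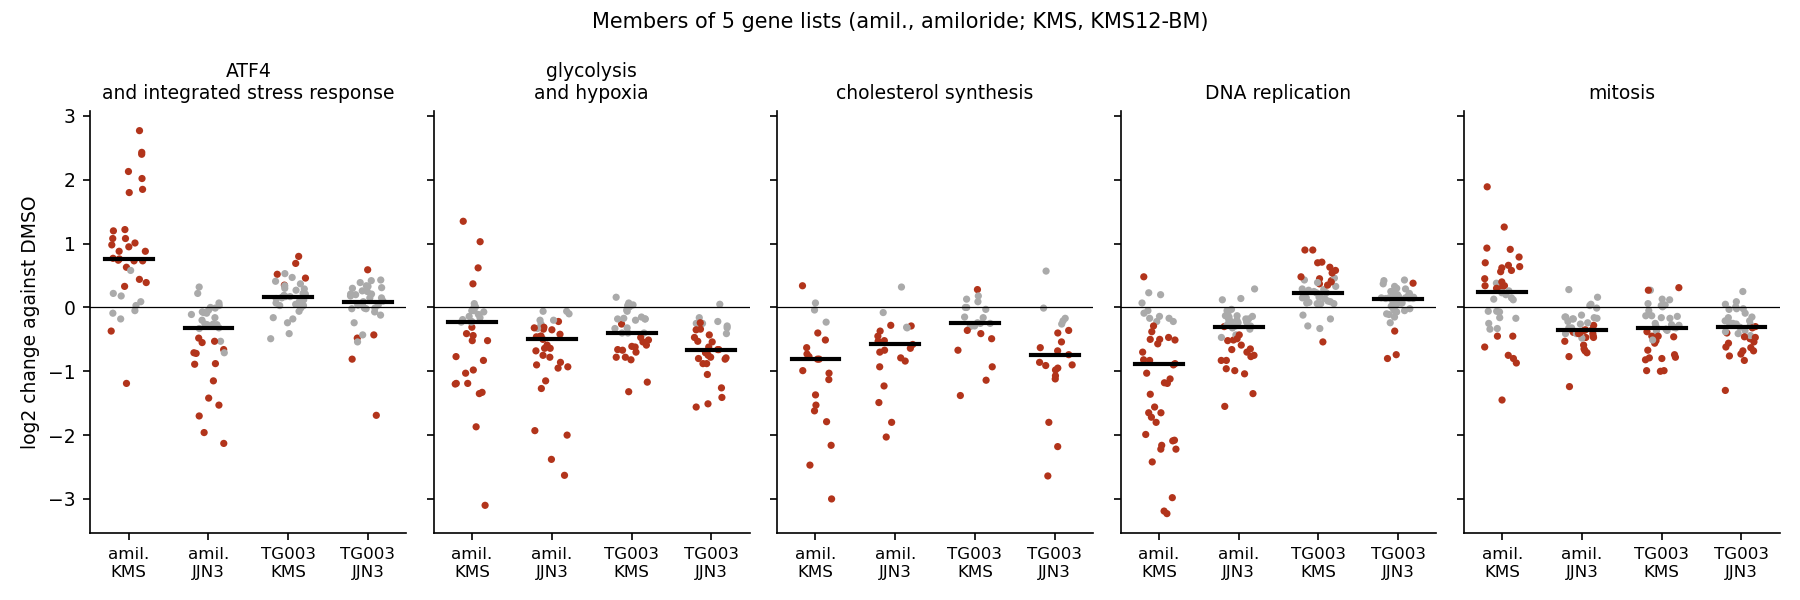
Log2 change against DMSO (vertical) of each member of 5 gene lists under the 2 drugs in the 2 lines, with called members in red, others in grey and the list median as a bar. Integrated stress response genes have medians of 0.76 in KMS12-BM and -0.32 in JJN3 under amiloride, and DNA replication genes have medians of -0.88 and -0.30.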

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

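The tests that left out single DMSO arrays were divided by list and comparison after their result was seen. The scaling of single lists was chosen after seeing the data. The other tests of causes address patterns already seen in these data, with limits set before the test values were computed. The splits of the arrays were set out before they were counted.

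The amiloride response differed between the lines for 4148 genes by a test of the difference, JJN3 minus KMS12-BM. Among single genes, the response in JJN3 was higher by 3.85 for SLA2, 2.99 for LPCAT3, 2.95 for SEPTIN3, 2.91 for TMT1B and 2.89 for TAF9B. It differed by -3.58 for CTH, -3.57 for TCP11L2, -3.39 for KMO, -3.33 for KLHL24 and -3.15 for BRI3. The size is uncertain for all of these but LPCAT3, TAF9B and KLHL24, since at least 1 of the 4 group means lay below the background reference. For SLA2, SEPTIN3 and TMT1B one line lay below it already with DMSO, so a fall there could be missed. Among lists tested the same way, median differences were -1.39 for the integrated stress response, -0.56 for NF-kB targets, -0.49 for snoRNA host and nonsense-mediated decay RNAs, -0.48 for mitosis, -0.23 for glycolysis and hypoxia and -0.19 for CLK, DYRK and SRPK kinases, of which the last pair shrank to -0.13 and -0.10 after a further quantile normalization. They were 0.67 for AHR targets, 0.47 for MYC targets and ribosome biogenesis, 0.40 for DNA replication, 0.36 for cholesterol synthesis, 0.27 for the proteasome, 0.19 for heat shock and 0.13 for oxidative stress under NRF2. With an estimated correlation only the AHR targets kept their call (adjusted p = 0.032), and the other lists had an adjusted p of 0.1 to 0.65. For the AHR targets that estimate was -0.09, below the preset 0.01, so for them the second test was not stricter on correlation. Without KMS12-BM DMSO array 2 the adjusted p was 0.06 for cholesterol synthesis and 0.095 for heat shock. The heat shock call also ended without JJN3 DMSO array 3 (adjusted p = 0.11) and KMS12-BM amiloride arrays 1 (0.059) and 3 (0.055). The call of snoRNA host RNAs ended without JJN3 amiloride array 3 (adjusted p = 0.055), JJN3 DMSO array 2 (0.05) or KMS12-BM amiloride array 2 (0.054), or with quantile normalization (0.056).

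Under amiloride 25 of 35 integrated stress response genes rose in KMS12-BM and 14 of 35 fell in JJN3, where 21 did not pass, with a median difference of -1.39, but the lists of both lines and of the difference lost their calls with an estimated correlation (adjusted p = 0.3, 0.27 and 0.1). The third KMS12-BM amiloride array is argued against as the source by a median difference of -1.41 without it, which does not test its label. The scaling of arrays is argued against by a difference of -1.35, the weaker value after centring and after quantile normalization. None of 10000 random lists of matched brightness reached so low a difference (percentile 0), which argues against a trend with brightness. Line and dose cannot be told apart, since 0 lines were measured at both doses. The opposite direction may therefore reflect the lines, the doses or the serum share of the medium, which also differed with the line.

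Glycolysis and hypoxia genes and cholesterol synthesis genes had negative medians and passed at the preset correlation under both drugs in both lines, but in KMS12-BM these 4 calls were lost with an estimated correlation (adjusted p = 0.3 and 0.081 under amiloride, 0.094 and 0.31 under TG003). A trend with brightness is argued against, since the highest of the 8 percentiles among random lists of matched brightness was 0.12. A single DMSO array is argued against as the source of the glycolysis falls, which kept at least 76.5% of their median (-0.51 for TG003 in JJN3 without JJN3 DMSO array 3), and of the cholesterol falls outside TG003 in KMS12-BM, which kept at least 94.2%. For cholesterol genes under TG003 in KMS12-BM, 45.2% of the median was left without KMS12-BM DMSO array 2 (-0.11 against -0.25), so much of that fall may come from this array, although the list call held (highest adjusted p = 0.016). A shared drug response of the lines stays open as a hypothesis for the others. Both drugs in a line share the same 3 DMSO arrays, so their falls are not independent. Leaving out single arrays cannot show a state common to all DMSO arrays of a line.

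Amiloride changed 6865 genes in KMS12-BM at 0.1 mM and 3317 in JJN3 at 0.4 mM. A smaller SE from tighter replicates in KMS12-BM is argued against as a cause, since the model shared each gene's variance across all groups. A gene therefore had the same SE in both lines. After the same noise term was subtracted for both lines, the SD of the log2 changes was 0.475 in KMS12-BM and 0.246 in JJN3. Their ratio of 1.93 shows larger changes in KMS12-BM but does not correct for spread particular to a line. The third KMS12-BM amiloride array is argued against as the source, since 6080 genes were called without it. This count does not test its label. With 0 lines measured at both doses, line and dose cannot be told apart, and a lower sensitivity of JJN3 may or may not be behind the difference. The serum share of the medium differed with the line as well.

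The TG003 response differed between the lines for 1026 genes by a test of the difference. Single genes differed by 2.58 for SLA2, 2.04 for CD27, 2.03 for HES1, 1.99 for SEPTIN3 and 1.96 for TMT1B, and by -3.37 for CCL2, -3.30 for AMPD1, -2.98 for HBBP1, -2.69 for CCL3, -1.92 for IGF1 and -0.72 for CLK3. For each of these genes but CLK3, one line lay below the background reference with DMSO and with TG003. A change in that line could be missed, so the difference itself and its size are uncertain. Median differences of lists were -0.58 for cholesterol synthesis, -0.19 for glycolysis and hypoxia, -0.19 for cytosolic ribosomal proteins, -0.17 for DNA replication, -0.07 for heat shock, 0.33 for MYC targets and ribosome biogenesis and 0.06 for endoplasmic reticulum chaperones. None of these 7 lists kept its call with an estimated correlation (adjusted p = 0.13 to 0.97). Without JJN3 TG003 array 3 the adjusted p was 0.17 for heat shock and 0.099 for DNA replication. The heat shock call also ended without JJN3 DMSO arrays 1 (0.052) and 2 (0.095) and KMS12-BM DMSO arrays 1 (0.054) and 3 (0.097). The heat shock and DNA replication calls also ended with quantile normalization (0.18 and 0.094), and the chaperone call with arrays centred on their median (0.051). The chaperone call ended without JJN3 DMSO array 3 (adjusted p = 0.064), JJN3 TG003 arrays 1 (0.077) and 2 (0.23), KMS12-BM DMSO arrays 1 (0.084) and 2 (0.081) or KMS12-BM TG003 array 3 (0.17).

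Other splits of the arrays were counted for each comparison. For the amiloride response, 1 of 100 splits, the real one, reached 4148 genes, and the highest other gave 4026. For the TG003 response, 1 of 100, the real one, reached 1026, and the highest other gave 912. The splits that came near kept the labels of KMS12-BM and mixed those of JJN3, whereas those that mixed the labels of KMS12-BM gave at most 255 and 252, so these counts exclude arrays without any drug response and not equal responses of the lines. For comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05. The real and highest other counts were 6865 and 0 for amiloride in KMS12-BM, 3317 and 2 for amiloride in JJN3, 3330 and 0 for TG003 in KMS12-BM, 2107 and 10 for TG003 in JJN3, 9258 and 0 for the lines, 6686 and 0 for the drugs in KMS12-BM, and 3807 and 1 for the drugs in JJN3.

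In data outside the gene comparisons, the control probe set ERCC-00145 read 12.89 on JJN3 TG003 array 2, above the JJN3 DMSO arrays at 9.17 to 9.84 and the range of 7.77 to 10.64 on the other 17 arrays. On the same array ERCC-00014 read 14.68 and ERCC-00099 read 10, against means of 15 and 10.46, so these controls were not raised there. Groups of 3 were not tested for single arrays far from the others. Array weights were lowest for JJN3 TG003 arrays 3 (0.38) and 2 (0.41), against 2.79 for the first array of that group.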

How the results depend on the processing

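The alternatives in this part were planned, except the scaling of single lists, which was chosen after seeing the data. Of 1129 named-gene results, 927 kept their direction and side of the threshold under all alternatives run, 200 lost the call in at least 1, 1 gained it and 2 reversed, of which HNRNPR is also among the 200. HNRNPR under TG003 in KMS12-BM was -0.02 (-0.019) with the mean of its probe sets. SCNN1A under amiloride in JJN3, 0.00 in the report, was 0.028 with arrays centred on their median, 0.031 with quantile normalization, and -0.024 to 0.021 with single arrays left out (0.01 without JJN3 DMSO array 1, 0.009 without DMSO array 2, 0.021 without amiloride array 2), all within its SE of 0.05. Counts of called genes stayed within 1.5 times the reported ones under every alternative run on all arrays except array weights, which gave 3581 for TG003 in JJN3, 2262 for the TG003 response between lines and 5872 for amiloride against TG003 in JJN3, and the cause was not tested. With single arrays left out, the TG003 response between lines gave 677 genes without JJN3 DMSO array 2 and 679 without KMS12-BM DMSO array 1, up to 992, where fewer arrays are compared. The other counts moved less, for example to between 6031 and 6530 for amiloride in KMS12-BM and to between 1465 and 1841 for TG003 in JJN3. All probe sets, named or not, gave 12475 calls for amiloride in KMS12-BM, 4216 for amiloride in JJN3, 5658 for TG003 in KMS12-BM and 2895 for TG003 in JJN3.

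Called lists were most sensitive to the correlation assumed between genes. With an estimated correlation 0 of 15 remained for amiloride in KMS12-BM, 3 of 19 for amiloride in JJN3, 0 of 15 for TG003 in KMS12-BM, 4 of 14 for TG003 in JJN3, 1 of 8 for the lines, 1 of 13 and 0 of 7 for the responses to amiloride and TG003 between lines, and 0 of 11 and 2 of 15 for one drug against the other in KMS12-BM and JJN3. The estimate was -0.09 for AHR targets and -0.01 for the MAF-translocation signature, below the preset 0.01. Calls of these lists therefore do not show that they withstand a higher correlation. It was 0.14 for glycolysis and hypoxia, 0.16 for cholesterol synthesis and 0.1 for plasma cell markers. For the lines, ranks gave 5 lists, and single arrays left out gave 5 (without JJN3 DMSO array 2) to 8. DNA replication lost its call between the lines without KMS12-BM DMSO array 3 (adjusted p = 0.065) or JJN3 DMSO array 2 (0.054), cytosolic ribosomal proteins without any of 4 arrays, up to 0.13 (KMS12-BM DMSO array 2), and immediate early genes without any of 4, up to 0.084 (JJN3 DMSO array 3). Among 117 called lists over all contrasts, centring ended 4 calls, and quantile normalization ended 14 without a change of direction. Beside these it reversed 2 medians of SR splicing factors, to -0.01 for amiloride in KMS12-BM, where the call ended too, and -0.02 for amiloride against TG003 in JJN3. The cause was not tested. Overlaps fell with stricter thresholds by construction. At an adjusted p under 0.01, and with at least 2-fold changes, amiloride in both lines shared 719 and 24 rises and 479 and 57 falls, TG003 in both lines 184 and 14 rises and 232 and 12 falls, the drugs in KMS12-BM 483 and 24 rises and 467 and 49 falls, and the drugs in JJN3 122 and 3 rises and 242 and 40 falls. Without the third KMS12-BM amiloride array the amiloride overlap was 1174 rises and 731 falls. The background reference was exceeded by 8315 of 22465 genes in at least 1 group, but calls were not confined to such genes. A group mean lay above it for 69.6% of the genes called for amiloride in KMS12-BM and 63.2% of those called between the lines.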

Other observations

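The tests of gene classes in this part were chosen after such genes were noticed among the largest changes in these data, and before the class values were computed.

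Some named genes were not given in the comparisons above. Under amiloride in KMS12-BM, DNA damage repair genes went both ways, with FANCI at -2.55, PALB2 at -2.01 and RAD50 at 2.35, and the downward list call (adjusted p = 0.033) ended without KMS12-BM DMSO array 2 (0.15) or amiloride array 1 (0.051), and with an estimated correlation (adjusted p = 0.77). The autophagy gene WIPI1 rose by 1.9 and MAP1LC3B by 1.46, and the cystine carrier gene SLC7A11 rose by 1.22 while the oxidative stress genes TALDO1 and TXNRD1 changed by -1.50 and -1.01. The list of 24 p53 target genes did not pass there, with 5 up, 5 down and a median of -0.06 (adjusted p = 0.91). Under amiloride in JJN3, HLA-DQA1 changed by -1.34 and MZB1, a chaperone of antibody secretion, by -1.14. Under TG003, the interferon-induced membrane genes IFITM2 and IFITM1 changed by -1.51 and -1.27 in JJN3, where the interferon list did not pass (adjusted p = 0.064), and in KMS12-BM ITGB7 changed by -1.80, BTK by -1.15 and MYC by -0.56 ± 0.12 (adjusted p = 0.0048).

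A first hypothesis is that transcripts named as divergent (-DT) or antisense (-AS) RNAs may rise as a class under TG003. Of 847 such genes 85 rose and 9 fell in KMS12-BM, and 37 rose and 6 fell in JJN3. The shares that rose, 10% and 4.4%, were near the 8.3% and 3.7% of all genes, while those that fell, 1.1% and 0.7%, were below 6.5% and 5.6%. The class median was above all 10000 random lists of matched brightness in each line (lower percentile 100), but it was small, at 0.004 in KMS12-BM and 0.047 in JJN3. Under amiloride 65 rose and 64 fell in KMS12-BM, where the percentile was 1.63, and 24 rose and 16 fell in JJN3, where it was 61.79. Shares that rose and fell were 7.7% and 7.6% in KMS12-BM, against 17% and 13.6% of all genes. In JJN3 they were 2.8% and 1.9%, against 8.6% and 6.1%, so the class was called less often in both directions.

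A second hypothesis is that genes named ZNF, most of which encode zinc finger proteins, may rise as a class under TG003. Of 452 such genes 120 rose and 10 fell in KMS12-BM, with a median of 0.146, and 26 rose and 11 fell in JJN3, with a median of 0.05 (lower percentile 100). The shares that rose were 26.5% and 5.8%, against 8.3% and 3.7% of all genes. Amiloride gave 173 rises and 36 falls in KMS12-BM (median 0.152, percentile 100) and 37 rises and 17 falls in JJN3 (median 0.028, percentile 99.7). With amiloride 38.3% rose in KMS12-BM, against 17% of all genes, and 8.2% in JJN3, against 8.6%. By the class median, the shift was therefore not specific to TG003 in either line. In JJN3 the share of rises under amiloride was not above that of all genes, but falls were fewer, at 3.8% against 6.1%. Genes of a class are not independent, and random lists do not carry their correlation.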
